A study of Homo sapiens with 18 samples.

How the data were processed

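The data are guide counts from a pooled CRISPR interference screen, in which dCas9 fused to the KRAB repressor is directed to promoters by guide RNAs and silences transcription there. The screen was run in A431 cells, a human epidermoid carcinoma line, and Cal27 cells, a human tongue squamous carcinoma line. Per the labels' protocols, infected cells were selected with puromycin, collected in triplicate before injection (week 0) and injected into both rear flanks of 3 mice per line. Tumors were harvested at 3.5 weeks for A431 and 4.5 weeks for Cal27. The protocol names SCID hairless outbred mice, whereas the design text calls them nude.

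The deposited values are whole-number counts per guide, with no normalization by the authors that the files show. Per the submitters' processing notes, hg38, cutadapt, Bowtie, UMI-tools and MAGeCK were used; their versions and settings are not given in the sources used here. Whether a count is a read or a unique molecule is not stated either, so counting error is a lower bound on the technical error. The labels list 18 samples, with 6 tumors from 3 mice and 3 week 0 collections per line. The tables hold 12 columns that match these groups, 3 tumor columns and 3 week 0 columns per line, and how 6 tumors became 3 columns is not stated. A tumor column was therefore taken as a replicate of its group without a mouse or flank assigned to it. The 2 plasmid columns, 1 per table, match no sample in the labels and were not used here.

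Both tables list the same 2000 guides. Of these, 1760 target 176 promoter windows of 67 named transcripts, 140 target 14 protein genes, and 100 are safe-targeting controls that each stand alone. Every window and gene has 10 guides. Window coordinates are those in the files, on hg38, and were compared with RefSeq gene positions on GRCh38. Of the 84 windows whose name RefSeq holds, 66 lie within 10 kb of the gene of that name. Of the windows, called lncRNA windows here after the kind of target the study names, 11 carry a symbol that RefSeq lists as protein-coding (KCP, PLK1S1, now KIZ, and LINC00094, now BRD3OS). Guide sequences and the genome were not used here, so matches of a guide to a second site could not be examined. This matters for LINC00152 (CYTOR in RefSeq) and MIR4435-1HG (MIR4435-2HG in RefSeq), which are near-identical copies and are reported as uncertain for that reason.

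Guide counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), separately in each line, tumor against week 0. The filter removed 0 guides in A431 and 0 in Cal27. The difference between the lines was the interaction term of a fit over all 12 columns. One-sided guide p-values were combined per target by alpha robust rank aggregation, written after the MAGeCK method, with alpha 0.25, at least 3 guides and 200000 random guide sets, so that the smallest p is 5e-06. Unless another test or alternative is named, adjusted p-values for targets below come from this aggregation of edgeR p-values with Benjamini-Hochberg adjustment over 190 targets in each direction, at a threshold of 0.05. The effect of a target is the median over its 10 guides of the edgeR log2 fold change. A second summary, the column value, is the median over guides of log2(CPM + 1) in a tumor column minus the week 0 mean, given as mean ± SD over 3 columns. The first averages counts and the second averages logarithms, and the second takes the median over guides within each column. The 2 summaries can therefore differ even where the columns agree, as for ITGB1 in Cal27 (-0.42 against -0.64 ± 0.03). limma 3.58.1 (fry, voom) and DESeq2 1.42.0 served for gene lists and alternatives, each adjusted over its own targets, and windows pooled per transcript were adjusted over 81 targets, and Python 3.11.15 with matplotlib 3.10.9 for annotation and figures.

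The comparisons, the gene lists and most alternatives were fixed before the data were examined. They assumed 6 separate tumor libraries per line, to be summed per mouse; the tests were kept and run on the 3 columns. Named targets are, per line and direction, up to 12 targets past the threshold with the largest effect, or the 4 with the smallest p where fewer than 4 passed. Added to these are targets shared by both lines, up to 6 per direction in the line difference, and up to 4 members of each list. SMARCA4, CDKN2B, H19 p007 and CATG00000116321.1 p002 fall outside this rule and were named after their values were seen, the first pair to complete the protein genes and the others because a guide in them passed. List members were matched by the names in the files.

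The fits were tested on simulated counts with the means, depths and spreads of the real groups, in 10 runs with 20 of 190 targets (200 of 2000 guides) changed. At a simulated log2 fold change of -1, 100% of changed targets were recovered for A431 and 100% for Cal27. At -0.5 the shares were 70% and 96%, and at 0.5 they were 70% and 88%. False target calls over the 10 runs numbered 2 for A431 and 0 for Cal27. For the difference between the lines, 100% were recovered at -1, 44% at -0.5 and 32% at 0.5, with 1 false call. The simulation gave all guides of a group 1 common spread, which real tumors need not follow. It also gave the 10 guides of a changed target the same effect. Recovery of targets with only a few active guides was therefore not tested, and these shares may be too high for them.

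Alternatives covered the normalization, the count filter, DESeq2's Wald test, other target tests, the threshold, a replicate block and each column left out in turn. Those that need single tumors or mice could not be run. Week 0 columns are repeat collections of a cell pool and nothing states separate cultures, so p-values measure only the spread between these samples, which may be technical.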

Results

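The screen asked which promoters, when silenced, changed the abundance of squamous carcinoma cells during tumor growth in mice. Guide counts were compared between 3 tumor columns and 3 week 0 columns in each of the lines A431 and Cal27. Total counts ran from 4586092 to 6044713 in the 6 week 0 columns and from 7500213 to 9275337 in the 6 tumor columns. Every guide was counted in every column, with a lowest tumor count of 24 in A431 and 33 in Cal27. Levels of the silenced transcripts were not measured in these data.

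In A431 tumors 4 targets fell relative to week 0. DUT, the enzyme that keeps uracil out of DNA, fell furthest, with a median guide log2 fold change of -1.05 and column values of -1.08 ± 0.39 (SD, n = 3; adjusted p = 0.00095). FOSL1, a subunit of the AP-1 transcription factor, was at -0.60, with columns at -0.77 ± 0.41 (adjusted p = 0.0146). MCM5, part of the replicative helicase, was at -0.48, with columns at -0.75 ± 0.53 (adjusted p = 0.0152). The lncRNA window that passed was LINC00152 p005, on chromosome 2 from 87455401 to 87456051 (hg38), which overlaps CYTOR, LINC01943 and NCAL1 in RefSeq. It was at -0.60, with columns at -0.66 ± 0.24 and 8 of 10 guides lower (adjusted p = 0.0146). Each of the 4 was lower in 3 of 3 columns.

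The A431 calls differed in how they fared under alternatives, and leaving out a column also leaves fewer columns to test. DUT passed in every alternative run (adjusted p from 0.00017 to 0.0364), at -0.63 with guides under a week 0 mean of 2000 left out. LINC00152 p005 stayed between -0.84 and -0.45 without any single column, but did not pass without tumor column 2 (-0.48, adjusted p = 0.194) or 3 (-0.45, 0.104), nor with fry (0.108) or limma (-0.55, 0.0644), over a range of 0.00133 to 0.194. With the 50 guides of all LINC00152 windows pooled, an alternative chosen after seeing the data, the A431 median was 0.02 and did not pass (adjusted p = 0.297). FOSL1 did not pass without tumor column 3 (-0.43, adjusted p = 0.569) or with fry (0.0801; range 0.00133 to 0.569). MCM5 did not pass without tumor column 2 (-0.48, adjusted p = 0.338), tumor column 3 (-0.26, 0.569) or week 0 column 1 (-0.45, 0.0703), with fry (0.169), limma (0.112) or guides under a week 0 mean of 2000 left out (0.132), and was at -0.90 without tumor column 1 (range 0.00443 to 0.569). The count of 4 was 1 without tumor column 3 and 7 without week 0 column 2.

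GINS1, another replication factor, had the lowest A431 column values, -1.47 ± 0.26 (SD, n = 3), with a median guide value of -0.88 that did not pass (adjusted p = 0.262). It passed with fry (adjusted p = 0.00594), limma (0.0005), the median guide test (0.000317) and a replicate block (0.0019), and without week 0 column 2 (0.0459). TP63, the lineage transcription factor of squamous epithelium, was at -0.73 and did not pass (adjusted p = 0.0885), but passed with the median guide test (0.000317), a replicate block (0.00253), windows pooled per transcript (0.0472, from the same guides and p adjusted over 81 targets in place of 190), and without tumor column 2 (0.0223) or week 0 column 1 or 2 (0.0404 and 0.0459). In the other direction 0 targets passed in A431 by rank aggregation of edgeR p-values, 15 had an unadjusted p under 0.05, fry called 5, and aggregation of DESeq2 p-values called 0. The 4 with the smallest p were AC034220.3 p003, which overlaps SLC22A5 and MIR3936HG (median guide value -0.000055, adjusted p = 0.104), CATG00000061516.1 p001 (0.47, 0.114), AC017048.3 p005 in LINC01116 (0.43, 0.168) and AC012363.4 p003 (0.34, 0.168). AC034220.3 p003 had 5 guides on each side of 0, and it was the 1 target that passed without week 0 column 2 or 3.

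In Cal27 tumors 8 targets fell, and each of them was a protein gene. FOSL1 fell furthest at -1.69, with columns at -1.68 ± 0.40 (SD, n = 3), or 31.3% of the week 0 abundance (adjusted p = 0.000237). TP63 followed at -1.50, with columns at -1.51 ± 0.19, and JUNB, another AP-1 subunit, at -1.06, with columns at -1.02 ± 0.40 (both adjusted p = 0.000237). HAUS1, of the augmin complex of the mitotic spindle, was at -0.90 (columns -0.99 ± 0.25, adjusted p = 0.00174). GINS1 was at -0.69 (adjusted p = 0.0417), the growth factor receptor EGFR at -0.58 (0.0166), DUT at -0.57 (0.00057) and the integrin ITGB1 at -0.42 (0.000237). Each of the 8 was lower in 3 of 3 columns.

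FOSL1, JUNB, DUT and ITGB1 passed in every alternative run in Cal27, with a highest adjusted p of 0.0269. DUT was at -1.07 and GINS1 at -1.25 without tumor column 2. EGFR did not pass without tumor column 1, 2 or 3 (adjusted p = 0.108, 0.0843 and 0.17), although its fold stayed at -0.52, -0.63 and -0.73. HAUS1 did not pass without column 1 or 2 (0.0556 and 0.0588, at -0.92 and -0.63). GINS1 did not pass without column 1 (0.93, at -0.48), with scaling on the safe guides (0.0606), with total counts (0.0811) or with an alpha of 0.5 (0.0536). With guides under a week 0 mean of 2000 left out, an alternative chosen after seeing the data, TP63 was at -0.41 (adjusted p = 0.181), EGFR at -0.33 (0.517), FOSL1 at -0.91 (0.0141) and ITGB1 at -0.14 (0.00094). This filter drops the scarcest guides, which within depleted protein genes also tended to fall further in tumors. It can thus weaken a target by taking out its strongest guides. The adjusted p ranged over the alternatives from 2.34e-05 to 0.181 for TP63, 0.000158 to 0.517 for EGFR, 0.000158 to 0.0588 for HAUS1 and 0.00019 to 0.93 for GINS1.

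NOTCH3, a Notch receptor, was the only target that rose in Cal27 by rank aggregation, at 0.44 with columns at 0.44 ± 0.01 (SD, n = 3), higher in 3 of 3 columns and by 8 of 10 guides (adjusted p = 0.00285). Without tumor column 1, 2 or 3 it was as high or higher, at 0.53, 0.46 and 0.55, but did not pass (adjusted p = 0.0974, 0.165 and 0.123). NOTCH3 did pass without week 0 column 1, 2 or 3, so the number of columns alone does not account for the lost calls. Its adjusted p ranged over the alternatives from 0.000652 to 0.165. MCM5 was at -0.49 in Cal27 and did not pass (adjusted p = 0.185), but passed with fry (0.00794), limma (0.000139), the median guide test (0.00095) and a replicate block (0.00496), and without week 0 column 2 (0.0369). The chromatin remodeler SMARCA4 was at 0.22, the cell cycle inhibitor CDKN2B at 0.14, the cadherin FAT1 at 0.29 and NOTCH1 at 0.18, and none of these 4 passed in either line.

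**Figure D1:**
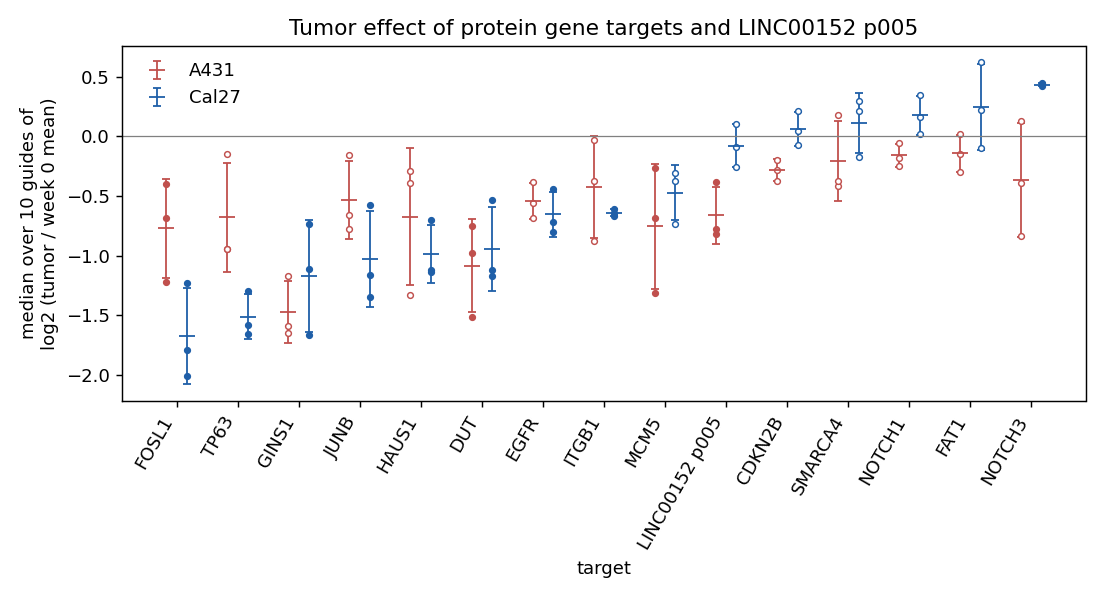
Median over 10 guides of log2 abundance in a tumor column over the week 0 mean (vertical axis) for 14 protein genes and LINC00152 p005 (horizontal axis); dots are the 3 tumor columns, filled where the target passed 0.05 in that line, with the mean and SD as bars. FOSL1 lies at -1.68 in Cal27 and -0.77 in A431, and NOTCH3 at 0.44 and -0.37.

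Protein genes fell more often than lncRNA windows. In A431 3 of 14 protein genes and 1 of the lncRNA windows passed (two-sided Fisher's exact p = 0.00124), and in Cal27 8 of 14 and 0 windows (p = 8.28e-11). In Cal27 4 windows had an unadjusted p under 0.05 for a fall and 6 for a rise by rank aggregation of edgeR p-values, while fry called 14 targets lower and 3 higher, protein genes included. For a rise, the windows with the smallest p, whatever their median, were CTB-140J7.2 p004 at 0.33, KCP p003 at 0.30 and PTPRG-AS1 p003 at -0.03, with adjusted p of 0.469, 0.898 and 0.919. The protein genes were chosen for the library, so they are not a random set of genes.

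Among the gene lists, the squamous drivers EGFR, ITGB1 and TP63 fell in Cal27, 3 of 3 over all targets and 3 of 3 adjusted over the list alone. In A431 0 of 3 passed over all targets and 3 of 3 adjusted over the list alone; over all targets EGFR passed with fry (adjusted p = 0.00594) and limma (0.00127), and ITGB1 without week 0 column 2 (0.0459). Their median was -0.58 in Cal27 (permutation p = 0.0024, adjusted 0.022) and -0.38 in A431 (p = 0.0045, adjusted 0.027, but 0.0883 without tumor column 2). Of the essential genes GINS1 and MCM5, 1 of 2 passed in each line, MCM5 in A431 and GINS1 in Cal27, and 2 of 2 adjusted over the list alone. Their median was -0.68 in A431 (adjusted permutation p = 0.015, but 0.0564 without tumor column 2) and -0.59 in Cal27 (0.079, but 0.0103 without tumor column 2; by fry 0.0123). Of the suppressors FAT1 and NOTCH1, 0 of 2 passed in either line, also adjusted over the list alone, with medians of -0.07 in A431 and 0.24 in Cal27 (adjusted permutation p = 0.43 and 0.27). The permutations set each list against all targets, most of which are lncRNA windows. The median over all 14 protein genes was itself -0.35 in A431 and -0.53 in Cal27. The permutation p-values therefore do not show that drivers or essential genes fell further than other protein genes, which was not tested.

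The lists of lncRNA windows had medians between 0.03 and 0.19, and their counts adjusted over the list alone equalled those over all targets. Of 22 windows of cancer-related lncRNAs, 1 fell in A431, LINC00152 p005, and 0 in Cal27, with medians of 0.03 and 0.03 (adjusted permutation p = 0.43 and 0.43). In the same list LINC00152 p004 was at 0.11 in A431 and 0.30 in Cal27, LINC00152 p002 at -0.13 and 0.23, and H19 p002 at 0.21 and 0.08. With fry, LINC00152 p002 passed as lower in A431 (adjusted p = 0.0423), where p005 did not. Of 19 windows of skin and squamous lncRNAs 0 passed, with medians of 0.14 in A431 and 0.08 in Cal27 (adjusted p = 0.27 and 0.77). LINC00704 p002, p009 and p011 were at 0.38, 0.37 and 0.33 in A431 and MIR31HG p029 at 0.29; these LINC00704 windows lie over 10 kb from the RefSeq gene of that name. Of 7 windows of microRNA hosts 0 passed (medians 0.19 and 0.13, adjusted p = 0.27 and 0.43), with MIR31HG p024 at 0.22 and MIR4435-1HG p008 and p011 at 0.20 and 0.19 in A431. In the other direction, MIR31HG p024 was at -0.14 in Cal27 and passed as lower there with fry (adjusted p = 0.0312). Fry also called MIR4435-1HG p015 lower in A431. Of 36 antisense windows 0 passed (medians 0.03 and 0.05, adjusted p = 0.43 and 0.43), with MFI2-AS1 p007 at -0.42, MFI2-AS1 p003 at -0.25, TP73-AS1 p004 at 0.34 and TMPO-AS1 p001 at -0.27 in A431. Without A431 tumor column 1, MFI2-AS1 p003 was at -0.73 in A431 and passed by rank aggregation (adjusted p = 0.0228). Its difference, Cal27 minus A431, was then 0.88 and passed too (0.0443), against 0.40 with all columns (0.524). Of 22 LINC windows 1 passed in A431, again LINC00152 p005, and 0 in Cal27 (medians 0.10 and 0.06, adjusted p = 0.43 and 0.77).

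Of 92 windows with clone or accession names 0 passed, CATG00000041025.1 p002 at 0.50 and CATG00000049110.1 p013 at 0.45 in A431 included. Their median was 0.11 in A431, against 0.03 for the other targets, protein genes included (adjusted permutation p = 0.037), and 0.07 in Cal27 (0.46). The A431 difference did not pass without tumor column 1, 2 or 3 or week 0 column 3 (adjusted p = 0.0994, 0.0879, 0.555 and 0.144). For the cancer-related list fry pointed down in A431 (adjusted p = 0.0197) and Cal27 (0.113), opposite in sign to the list medians. It did so too for antisense windows (0.358 and 0.884), LINC windows in A431 (0.884), skin lncRNAs in Cal27 (0.878) and clone names in Cal27 (0.884). The median over all targets was itself above 0, at 0.07 in each line. Relative to the other targets, the cancer-related list was lower in A431 (0.03 against 0.07) and Cal27 (0.03 against 0.07), the direction of fry. The antisense windows were lower too (0.03 against 0.08, and 0.05 against 0.07). The LINC, skin and clone lists just named were higher than the other targets. Lists of small nucleolar RNA hosts, divergent and intronic transcripts had 0 members here.

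FOSL1 and JUNB fell further in Cal27 than in A431 by a test of the difference itself, in which 5 of 190 targets passed. FOSL1 differed by a median guide log2 value of -0.95, Cal27 minus A431 (adjusted p = 0.0171), and JUNB by -0.76 (0.0355). JUNB had a median of -0.04 in A431 but column values of -0.53 ± 0.33 (SD, n = 3), and its column values differed between the lines by -0.49, within the summed SDs of 0.73. NOTCH3, at -0.09 in A431, was higher in Cal27 by 0.73 (adjusted p = 0.0285), and LINC00152 p005, at -0.04 in Cal27, by 0.57 (0.0304). CATG00000049110.1 p011, on chromosome 2 from 78379006 to 78379656, differed by -0.49 (adjusted p = 0.0171), at 0.45 in A431 and -0.03 in Cal27, and passed in neither line alone as a window. TP63 differed by -0.59 and did not pass (adjusted p = 0.121), but was at -0.76 and passed without A431 tumor column 3 (0.0199), and its column values differed by -0.83, more than the summed SDs of 0.65. A431 tumors grew for 3.5 weeks and Cal27 tumors for 4.5 weeks, so line and time vary together.

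Without single columns the differences kept their direction, from -1.32 to -0.56 for FOSL1, -0.99 to -0.62 for JUNB, 0.65 to 0.85 for NOTCH3, 0.44 to 0.63 for LINC00152 p005 and -0.60 to -0.43 for CATG00000049110.1 p011, but each lost its call in some of these runs. FOSL1 did not pass without Cal27 tumor column 1 or 2 (adjusted p = 0.131 and 0.215) and was at -0.56 without A431 tumor column 2. JUNB did not pass without A431 tumor column 1 (0.395), A431 week 0 column 3 (0.0595), Cal27 tumor column 1, 2 or 3 (0.0712, 0.211 and 0.145) or Cal27 week 0 column 1 (0.0823), nor with scaling on the safe guides (0.0633). NOTCH3 and LINC00152 p005 did not pass without A431 tumor column 2 or 3 (0.271 and 0.18 for each) or Cal27 tumor column 1 or 3 (0.216 and 0.124 for each), and LINC00152 p005 also without Cal27 week 0 column 2 (0.0579). CATG00000049110.1 p011 did not pass without any of the 6 tumor columns (0.204 to 0.342). With windows pooled per transcript, adjusted over 81 targets, CATG00000049110.1 was at 0.31 in A431 and passed as higher (adjusted p = 0.0202) and differed between the lines by -0.21 (0.00405), while LINC00152 differed by 0.18 and did not pass (0.12). CTB-140J7.2 passed as higher in Cal27 when pooled (0.47, adjusted p = 0.0324); its window p004 differed by 0.52 and did not pass alone (0.0538), but did with scaling on the safe guides (0.0478) and without Cal27 tumor column 2 (0.0323) or week 0 column 1 (0.038). With guides under a week 0 mean of 2000 left out, FOSL1 was at -0.23 (0.436), and JUNB and CATG00000049110.1 p011 did not pass (0.0949 for each). The same filter drops scarce guides, which tended to fall further within depleted protein genes.

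DUT and FOSL1 fell in both lines, 2 shared targets where independent lists over all 190 targets would share 0.168 (one-sided Fisher's exact p = 0.00896). Among the 14 protein genes alone, 3 and 8 calls would share 1.71 by chance (one-sided Fisher's exact p = 0.615), so the overlap over all targets goes with protein genes being called more often. The number shared was 1 without A431 tumor column 3 and 5 without A431 week 0 column 2. Across 190 targets, which are not independent replicates, the median log2 fold changes of the lines had Pearson's r of 0.486 (permutation p = 1e-05, the smallest 100000 permutations can give, adjusted 3e-05) and Spearman's rho of 0.164 (p = 0.024, adjusted 0.072). Over the lncRNA windows r was 0.0796 (p = 0.3, adjusted 0.3) and rho 0.0953 (p = 0.21, adjusted 0.21). Over the 14 protein genes r was 0.579 (p = 0.031, adjusted 0.046), 0.780 without the 2 genes farthest from the A431 median, and rho 0.508 (p = 0.068, adjusted 0.1). These 3 relations form the family of adjusted values.

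**Figure D2:**
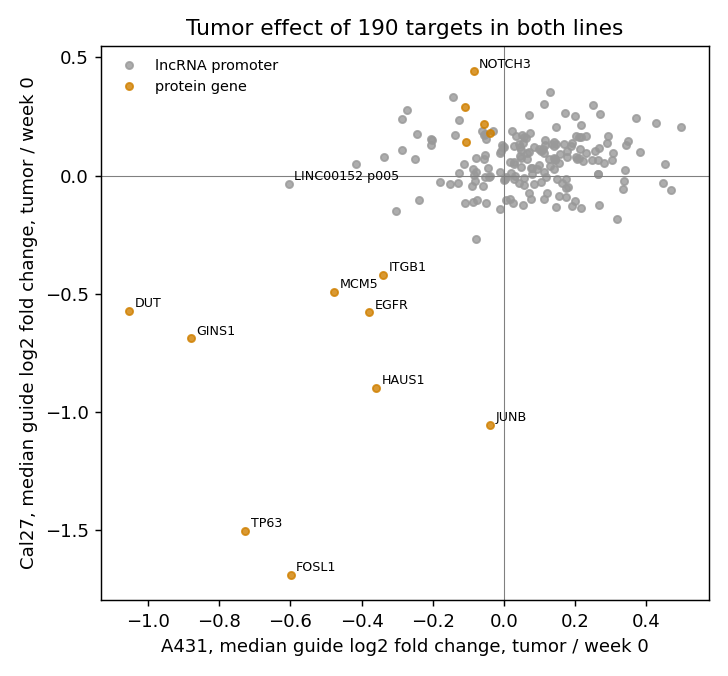
Median guide log2 fold change, tumor over week 0, of 190 targets in A431 (horizontal axis) and Cal27 (vertical axis); each dot is a target, and targets that passed 0.05 in either line are named. Pearson's r was 0.0796 over the lncRNA windows and 0.579 over the protein genes.

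Single guides passed the threshold in Cal27 and not in A431. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 15 Cal27 guides were lower, 4 against FOSL1, 3 DUT, 3 TP63, 2 ITGB1, 1 EGFR and 1 each in H19 p007 and CATG00000116321.1 p002. The deepest fall was a TP63 guide in Cal27 at -5.50 (SE 0.356, adjusted p = 0.00221). The 1 higher guide, in PTPRG-AS1 p003, was at 1.00. In A431 0 guides passed with edgeR, 254 had an unadjusted p under 0.05, and DESeq2's Wald test called 90. The Cal27 count of 16 was 136, 205 and 76 without tumor column 1, 2 or 3 and 1 without any single week 0 column, and the A431 count was 111 without tumor column 1 and 15 without tumor column 3.

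Safe-targeting guides gave the background. An unadjusted edgeR p under 0.05 was reached by 11 of 100 safe guides in A431 (95% exact interval 5.62% to 18.8%) and 8 of 100 in Cal27 (3.52% to 15.2%), where the intervals cover counting error only. Guides in lncRNA windows reached it in 205 of 1760 cases in A431 (two-sided Fisher's exact p = 1) and 225 of 1760 in Cal27 (p = 0.212), so no excess over the safe guides was detectable. Guides against protein genes reached it in 38 of 140 cases in A431 (Fisher's exact p = 0.00206) and 55 of 140 in Cal27 (p = 1.83e-08). The SD of guide log2 fold changes in lncRNA windows was 0.914 times that of safe guides in A431 (permutation p = 0.309) and 1.10 times in Cal27 (p = 0.314), and against protein genes 1.58 times (p = 0.00034) and 3.72 times (p = 1e-05, the smallest possible). The share of safe guides was 27%, 25% and 19% without A431 tumor column 1, 2 or 3 and 4% without any A431 week 0 column; for Cal27 it was 22%, 27% and 19%, and 2%, 1% and 1%.

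**Figure D3:**
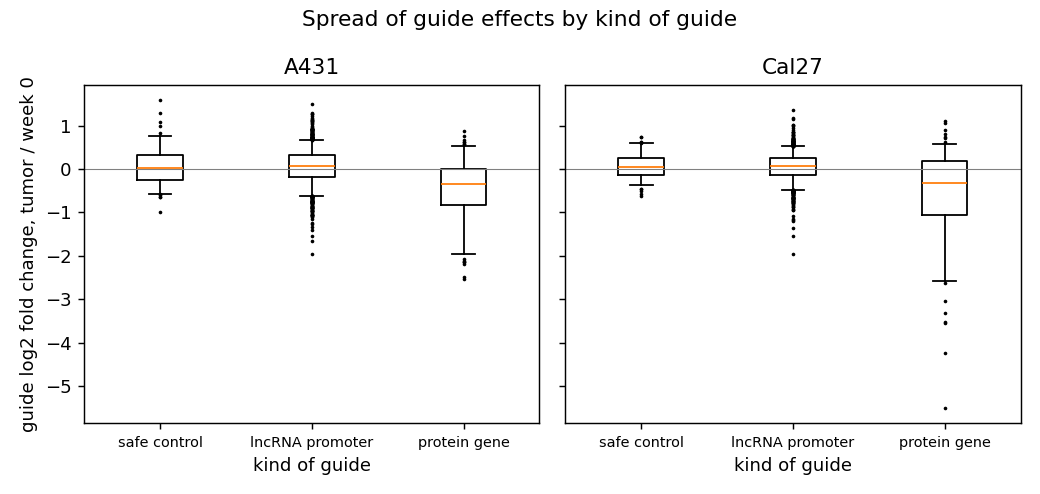
Guide log2 fold change, tumor over week 0, on the vertical axis for 100 safe guides, 1760 guides in lncRNA windows and 140 guides against protein genes in each line; boxes span the quartiles with the median as a line, whiskers run to the 5th and 95th percentiles, and dots are guides beyond them. The guides against protein genes reach down to -5.50 in Cal27 and -2.52 in A431.

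Guide abundance was more uneven in tumors than at week 0. In A431 the Gini index was 0.255 ± 0.0487 (SD, n = 3) in tumors and 0.0947 ± 0.00676 at week 0, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. In Cal27 it was 0.227 ± 0.0244 (SD, n = 3) against 0.0936 ± 0.00715, with the same exact p of 0.1. The biological coefficient of variation between columns was 39.7% in A431 tumors and 5.13% at week 0, and in Cal27 33.7% and 3.41%. The edgeR fit shares its spread between tumors and week 0, so a guide-level p-value averages over these unequal groups. Across guides, which are not independent replicates, Pearson's r between tumor columns was 0.182 to 0.284 in A431 and 0.299 to 0.372 in Cal27. Guides against protein genes reached 0.661 to 0.721 in Cal27 and 0.235 to 0.380 in A431, and guides in lncRNA windows 0.0447 to 0.114 and 0.118 to 0.224. Safe guides reached -0.0667 to 0.101 in Cal27 and 0.0942 to 0.326 in A431, where columns 2 and 3 had a higher r over safe guides (0.326) than over protein genes (0.235); the columns share the week 0 mean they are set against.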

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

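The test on growth time was chosen only after the result was seen. By the test of the difference, Cal27 minus A431, 5 targets differed between the lines: FOSL1 at -0.95, JUNB at -0.76, CATG00000049110.1 p011 at -0.49, NOTCH3 at 0.73 and LINC00152 p005 at 0.57. Of the 10 splits of the 6 tumor columns between the lines, 1 gave as many targets, the real one with 5, and the highest other gave 1; 10 splits are too few for a share under 0.05.

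FOSL1, JUNB and NOTCH3 differed between A431 and Cal27. The safe guides argue against guide noise of the size they show. Sets of 10 reached the largest p of the 3 genes in 84 of 200000 draws. This was at most 0.0988 sets over 190 targets (upper 95% limit), under a bound of 0.25. The sets reuse the same 100 guides, and the limit covers the draws alone. Guides against FOSL1, JUNB and NOTCH3 were scarcer than safe guides at week 0, at median log2 values of -0.12, -0.40 and -0.19 in A431 and -0.26, -0.53 and -0.19 in Cal27. Any added noise from that scarcity is not covered. Longer growth of Cal27 tumors, which would deepen falls, cannot be told apart from the line: of 9 protein genes depleted in either line 6 were lower and 3 higher in Cal27, and the largest rise, GINS1 at 0.30, was within the SDs of the columns. The bound for this test had been written for every called gene, and NOTCH3 meets it (0.80 against summed SDs of 0.50). Its columns in A431 were at -0.37 ± 0.48, which gave no sign of a gain there but lie within the SD of 0. NOTCH3 was picked for its difference between the lines, and a value beyond summed SDs is not a test. Growth time is therefore not excluded for NOTCH3. By column values, CDKN2B (-0.28 in A431, 0.06 in Cal27) and NOTCH1 (-0.16, 0.18) were also higher in Cal27 beyond the SDs. Both passed in neither line. Their median guide values in A431 and Cal27 were -0.11 and 0.14 for CDKN2B, and -0.04 and 0.18 for NOTCH1. A biological difference between the lines stays open and was not tested beyond this.

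LINC00152 p005 was lower in A431 tumors. The columns argue against a single tumor column, since the window lay at or below percentile 1.70 of the lncRNA windows in each of the 3, and the guides against 1 or 2 of them, since without its 2 lowest guides the rank aggregation p was 0.0130. Sets of 10 safe guides reached the p of the window with all 10 guides in 21 of 200000 draws, at most 0.0282 sets over the windows (upper 95% limit, same reservation), under a bound of 0.05. The number of draws was raised after a smaller first run fell just under that bound. Silencing of the 531 bp shared with LINC00152 p004 is argued against by p004 itself, at 0.11 where the 5th percentile of safe sets was -0.22. LINC00152 p004 overlaps the same RefSeq genes as p005, namely CYTOR, LINC01943 and NCAL1. Its value therefore gives no support to their silencing as the cause of the fall. Levels of these transcripts were not measured. Guides that match the near-identical MIR4435-1HG locus were not examined and stay open, and the window did not pass without tumor column 2 or 3, at -0.48 and -0.45 (adjusted p = 0.194 and 0.104, range over the alternatives 0.00133 to 0.194), or with the windows of LINC00152 pooled (0.02, adjusted p = 0.297).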

How the results depend on the processing

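The windows pooled per transcript, the filter at a week 0 mean of 2000 and the matching of list members through RefSeq synonyms were chosen after seeing the data. Not run, because 3 tumor columns stand for 6 tumors: each tumor as its own library, the mouse as a random block, leaving out single tumors, and tumors compared within and between mice. The filters at 100 counts and at none removed no guide and a minimum of 5 guides no target, so these test nothing and are left out of the counts that follow. The replicate numbers do not pair the columns (r of same-numbered deviations 0.00443 to 0.0681); with a replicate block the counts were 0 guides, 6 depleted and 0 enriched targets in A431, 14, 9 and 1 in Cal27, and 6 differences. Of the values of named targets under alternatives, 1886 stayed on the same side of the threshold, 53 lost the call and 52 gained 1. Only a result that passed in the main fit could lose its call, and most named results did not pass there. The 1886 therefore does not measure how stable the calls were. Some of the 52 gains came from the looser threshold alone. A change of direction was counted only where the target passed in the main fit or under the alternative. This held for 1 value, AC034220.3 p003 in A431 at 0.0051 with scaling on the safe guides. Unless given below, the cause was not tested. The lowest tumor count was 24; columns thinned to the smallest total gave Gini differences of 0.160 in A431 and 0.134 in Cal27 (0.160 and 0.133 unthinned), and the tests of guides and targets were not run on thinned counts.

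DESeq2's Wald test called 90 guides in A431 and 77 in Cal27, and a threshold of 0.25 called 17 and 81, with 7 depleted and 10 enriched targets in A431, 11 differences and 5 shared targets. With fry 8 targets fell and 5 rose in A431, and 14 fell and 3 rose in Cal27. The 2000-count filter left 1890 guides in A431 and 1837 in Cal27, with 7 guides and 4 depleted targets called in Cal27, 2 differences and 1 enriched target in A431; in Cal27 it left too few guides to test GINS1 and HAUS1. Safe-guide scaling gave 1 enriched target in A431, total counts 1 and pooled windows 3 (AC034220.3, CATG00000049110.1 and CATG00000061516.1). AC034220.3 and CATG00000061516.1 have 1 window each, so nothing was pooled for them. Their rank aggregation p-values were those of the main fit, adjusted over fewer targets (0.0221 and 0.0323, against 0.104 and 0.114). Only CATG00000049110.1 was pooled over several windows. The median guide test gave 5 shared targets. Synonyms brought the cancer lncRNA list to 25 windows, with a difference from all targets of -0.04 in A431 (adjusted permutation p = 0.341) and -0.02 in Cal27 (0.665).

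Leaving out a column in turn gave 0 to 111 guides in A431 and 1 to 205 in Cal27, 1 to 7 depleted and 0 to 1 enriched targets in A431, 5 to 9 and 0 to 1 in Cal27, 0 to 5 differences and 1 to 5 shared targets. Safe guides with an unadjusted p under 0.05 made up 4% to 27% in A431 and 1% to 27% in Cal27. List medians relative to all targets were 0.015 to 0.054 for clone or accession names, -0.87 to -0.53 for essential genes and -0.57 to -0.30 for squamous drivers in A431, and -0.96 to -0.57 for essential genes in Cal27.

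Each line's 6 columns allow 10 splits, too few for a share under 0.05. In Cal27 1 split, the real one, reached the 16 guides, 1 the 8 depleted targets and 1 the 1 enriched target, with 0, 0 and 0 as the highest others. In A431 1 split reached the 4 depleted targets, with 3 as the highest other; the real split had 0 guides and 0 enriched targets, so 10 and 10 reached as many, with 0 and 3 as the highest others.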

Other observations

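The tests on week 0 abundance were chosen only after the result was seen.

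Guides against the 9 protein genes depleted in either line were already scarcer than safe guides at week 0, with a median of 380.1 CPM against 493 in A431 and 383 against 497 in Cal27. HAUS1 and GINS1 were lowest, at -1.86 and -0.94 in A431 and -1.51 and -1.18 in Cal27 (median log2 relative to safe guides), but single genes overlapped: in A431 NOTCH3, which was not depleted, was at -0.19, below the depleted FOSL1 (-0.12) and ITGB1 (-0.15), and FAT1, SMARCA4, CDKN2B and NOTCH1 were at -0.02, -0.03, -0.07 and -0.07. Random sets of lncRNA windows did not depart as far from the safe guides, with a permutation p of 1e-05 in each line, the smallest 100000 draws can give. The scarcity thus exceeds the unevenness among lncRNA windows. This does not address uneven abundance of protein gene guides in the library itself, for which the unused plasmid columns would be needed. Within these genes the scarcer guides also fell further in tumors (pooled within-target Spearman's rho 0.522 in A431 and 0.631 in Cal27), and rho was 0.533 and 0.657 over the 74 guides left without those under 0.5 times the safe median (one-sided permutation p = 1e-05 in each line, the smallest possible), which argues against counting noise of these sparse guides; an excess of 0.180 over the 95% range of sets of 8 lncRNA windows decides nothing, since 14 and 10 of 1760 such guides were as sparse, against 16 of 90 here. Selection between infection and the week 0 collection is a candidate explanation, under which tumor against week 0 may understate the effect of these genes; the plasmid library was not used here.

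Guides of a target that were lower in A431 tended to be lower in Cal27. After removing target means, Pearson's r between lines across guides, which are not independent replicates, was 0.442 for the 140 guides against protein genes (permutation p = 2e-05, adjusted 3e-05) and 0.132 for the 1760 guides in lncRNA windows (p = 1e-05, the smallest possible, adjusted 3e-05). The 100 safe guides had an r of similar size, 0.122, that did not pass (permutation p = 0.223), so the lncRNA value was not shown to be specific to the windows.

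Windows within 1000 bp of a protein-coding gene had a lower median in A431 than the other windows, 0.04 over 91 windows against 0.13 over 85 (permutation p = 0.00132, adjusted 0.00264). In Cal27 the medians were 0.07 and 0.07 (permutation p = 0.618, adjusted 0.618), and the difference between the lines was not tested. The near windows in A431 were not below the safe guides, whose median was 0.015, so it is not shown that silencing of the nearby gene lowered the guides. As 57 windows overlap another and windows of a transcript lie together, the permutation p is too small.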
